A study of Mus musculus with 9 samples.

How the data were processed

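Host natural killer (NK) cells were measured by single-cell RNA sequencing in 5 mice, 2 controls and 3 with chronic myeloid leukaemia (CML). Per the labels, irradiated CD45.1+ recipients received CD45.2+ cells that carried the SCL-tTA/BCR-ABL transgenes or lacked the oncogene, and host NK cells (CD3-negative and positive for IL2Rb, NK1.1 and CD49b) were sorted from spleen and bone marrow 8 to 10 weeks later. Bone marrow and spleen cells of a mouse carried different hashtag antibodies and were loaded together, so the mouse is the replicate and both tissues of a mouse share a run. The labels say that CML mouse 1 gave too few marrow cells, which leaves 9 libraries, counted here as 1 per mouse and tissue. The planned depth was 50000 reads per cell for gene expression and 5000 for the hashtags, per the labels' protocols.

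The deposited matrices of 8 libraries hold whole-number UMI counts per gene and cell, not normalized, as their values show. The deposited matrix of control mouse 2 bone marrow names genes by symbol only and holds estimated counts, of which 0.055% of the entries are not whole. The sums over cells were rounded to whole numbers before every fit. That matrix lists 21979 gene rows, of which 22 (0.017% of its counts) could not be matched, and comparisons that use it were restricted to genes listed in every library. The names bcl2fastq, Cell Ranger, Partek and mm10 come from the submitters' processing notes, which give no version, and the filter the authors applied to barcodes is not given in the sources used here. Hashtag assignment to tissue was taken as deposited. Among cells passing the filter, the median bone marrow hashtag count was 2564 against a spleen hashtag count of 41 in control mouse 1 bone marrow. The reverse held in its spleen library, with 1914.5 spleen and 7 bone marrow hashtag counts. The 95th percentile of the wrong tissue's tag was at most 77 in control mouse 1 and CML mice 2 and 3. Control mouse 2 bone marrow carries differently named hashtags, with medians of 753, 148 and 32 and 95th percentiles of 821 and 325 for the second and the third, so its tissue assignment and freedom from doublets are less clear. The spleen libraries of control mouse 2 and CML mouse 1 hold no hashtag values, so their tissue could not be checked this way.

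Cells with at least 200 detected genes and under 10% mitochondrial counts were kept, 39373 in all. Scrublet, run within scanpy 1.11.5, called 30 of them doublets, between 0.0% and 0.45% of a library. Whether so few calls reflect few doublets or a caller that did not work was not tested, so doublets may remain. An alternative left out cells above 2 times the median UMI count of their library, which also takes out cycling cells. Counts were scaled to 10000 per cell, 1984 variable genes entered 30 principal components, and 15 nearest neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2) gave 22 clusters. A cluster was given a cell type from marker lists fixed before the data were examined, when at least 3 markers were detected at a median log2 fold of at least 1. Clusters named for a cell type other than NK or ILC1 were then removed, which left 21657 cells. Clusters 3, 6, 7 and 19 received no name and stayed in, with 4429, 2281, 2185 and 352 filtered cells. Their NK markers stood at median log2 folds of 0.41, 0.50, 0.29 and 0.20. Cells called NK-like below include these unnamed clusters. Among the removed clusters was cluster 4, named T cell-like with Cd3e, Cd3d and Tcrg-C2 among its top genes. It held 26.2% and 11.2% of the filtered bone marrow cells in control mice 1 and 2, and 41.6% and 19.0% in CML mice 2 and 3. Its NK markers stood at a median log2 fold of -0.67, against -2.72 to -4.86 in the other T cell-like clusters. Whether it holds NK cells stays open, and an alternative kept it.

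The rule that turned markers into names was rewritten after its results had been seen, and this decides which libraries enter the comparisons. The first version took the list with the highest median log2 fold. Another list was a rival if it had more markers among the cluster's top 10 genes. In every version, lists of NK, ILC1, cycling and interferon-stimulated cells did not rival each other. A rival left the cluster unnamed, or named for several myeloid types where no such list was involved. The second took the list with most markers among the top 10 genes and needed at least 2 markers for a rival. The third, used here, breaks ties by the share of markers detected. Versions 2 and 3 keep the same cells. Under version 1, cluster 10, led by Foxp3 and Il2ra with NK markers at a median log2 fold of -4.35, had no name and stayed in. It brought 812 cells of control mouse 2 spleen and 772 cells of CML mouse 1 spleen into the comparison. That cluster is ILC2-like under version 2 and T cell-like under version 3, and under both these spleen libraries keep 0 cells. Cluster 5 had no name under version 1 and is ILC1-like under versions 2 and 3. The total counts of changed genes that involve spleen therefore stand beside their values under version 1; counts per gene list and within clusters were made under version 3 and carry no such value.

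UMI counts of the kept cells were summed per library, giving between 5414908 and 29620759 counts in the 7 libraries with kept cells. Differences were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr) in R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values for single genes are from edgeR unless DESeq2 is named. The spleen comparison was planned with 5 libraries and rests on 3, with 1 control mouse, so its spread comes from the difference between 2 CML mice and from the trend over genes. Bone marrow was compared between 2 CML and 2 control mice. Spleen and bone marrow were compared within 3 mice with the mouse as a block; 4 mice had been planned, and control mouse 2 keeps no spleen cells. The difference of the CML effect between tissues was tested as an interaction in the same 3 mice, with 1 residual degree of freedom and a prior of 93.94 degrees of freedom taken from the trend over genes. The very small p-values of the interaction rest on that prior, and so do its standard errors. Each standard error was the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. In spleen the test has 1 residual and 6.257 prior degrees of freedom. For spleen and the interaction the standard errors are therefore not a measured spread between mice. The block comes from the labels, which state that both tissues are of one animal. Over 2924 genes, deviations from the tissue mean correlated at 0.344, 0.748 and 0.735 between tissues of one mouse, and between -0.589 and 0.191 for different mice. That mean is over mice of both conditions, which tends to push values between different mice below 0. Between CML mice 2 and 3, of one condition, they were 0.191 and 0.119. Both tissues of a mouse share a run, so these values do not separate animal from run. On simulated counts with 200 changed genes, the step recovered 88% of genes changed by log2 1 in the spleen design (11909 genes) and 86% in the bone marrow design (11132 genes). It recovered 100% in the tissue (11376 genes) and interaction (11687 genes) designs, and false calls were 3.1%, 0.5%, 3.4% and 6.1% in that order. The changed genes all had a mean of at least 50 CPM. Spread was simulated from the trend over genes alone, with no further spread of single genes or mice. The simulation checks the computation, and its rates are not those to expect in these data.

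The 28 gene lists were fixed before the data were examined and tested with limma 3.58.1 camera at a preset correlation of 0.01, then with an estimated correlation. The second form uses only the residual degrees of freedom, 1 for spleen and the interaction and 2 for bone marrow and between tissues. So few leave a list hardly able to pass. In spleen the proliferation list had an estimated correlation of 0.015, yet its unadjusted camera p went from 3.26e-18 to 0.0765. A call lost in that form therefore does not show that correlation explains a list. It does not exclude this either. In spleen the estimated correlation was 0.505 for the mature NK list and 0.75 for the ILC1 list. Between tissues it was 0.995 for the proliferation list. For such lists the preset form assumes far less correlation than was estimated, so its p-values may be too small. Preset p-values compare list genes with other genes and do not measure spread between mice. Some lists share members, so their results are not independent. Kit is in the immature NK, ILC1 and progenitor lists, and Il7r in the immature NK and ILC1 lists. S1pr5 and Cx3cr1 are in the mature NK and homing lists. Genes in the text follow a rule fixed at the same time as the lists. It takes genes past the threshold that separate the groups in every mouse and reach a mean of 50 CPM, and of these the 8 largest rises and 8 largest falls; up to 4 members of each list with the smallest p; 13 genes named in every comparison; and the 8 smallest p for the interaction. Gene models, ribosomal protein and mitochondrial genes are left out of the largest rises and falls. The text prints a selection of the genes this rule names, made after their values were seen. Shares of cells were compared by an exact two-sided permutation test over mice, with Wilson intervals at each library that cover counting error only. Folds against 0 counts use a floor of 3 counts in the library. Alternatives were DESeq2 1.42.0, other normalization, gene and cell filters, thinning to one depth, other clusterings, leaving out each mouse and other sets of cells. A fit without control mouse 1 was not possible for spleen or for the interaction. Leaving out a CML mouse there leaves no residual degrees of freedom in the main form, so all remaining libraries of both tissues were fitted as 4 groups without a block. The lone libraries of 3 groups are then assumed to vary like the 2 control bone marrow libraries. For bone marrow a lone library is assumed to vary like the other group. With the replicate number as a block, the spleen comparison could be fitted only on all cells.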

Results

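Host NK cells from spleen and bone marrow of mice carrying CML or control transplants were profiled by single-cell RNA sequencing. There were 2 control and 3 CML mice and 9 libraries, 4 from bone marrow and 5 from spleen. Total UMI counts ranged from 3595455 in control mouse 2 spleen to 37075945 in CML mouse 2 spleen. The remaining totals were 15703271, 27438516, 20437797 and 6965544 in the bone marrow of control mouse 1, control mouse 2, CML mouse 2 and CML mouse 3. In spleen they were 16947792 in control mouse 1, 3874932 in CML mouse 1 and 21992670 in CML mouse 3. After cells were filtered and clusters of other cell types removed, 1646, 3317, 1637 and 1351 bone marrow cells remained in that order, and 4850, 5345 and 3511 spleen cells in control mouse 1, CML mouse 2 and CML mouse 3.

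The spleen libraries of control mouse 2 and CML mouse 1 held no cells in NK-like clusters. Their median UMI counts per barcode were 361 and 272, against 2735.5 to 4338 in the other spleen libraries. Ncr1, the activating receptor that marks NK cells, stood at 3.62 and 11.1 CPM (counts scaled to the library total) over all barcodes, and at 499.1 to 1222 CPM in the other 7 libraries. Genes of the Y chromosome summed to 193.9 and 454.7 CPM there, and to at most 0.144 CPM elsewhere. The T cell gene Cd3e reached 354.3 and 451.4 CPM. Their cells lay in clusters largely apart from those of the other libraries. The T cell-like clusters 2, 9 and 10 held 44.7%, 16.4% and 15.4% of the filtered cells in control mouse 2 spleen. In CML mouse 1 spleen they held 61.6%, 17.0% and 14.5%. The NK marker genes summed to 1299 and 1319 CPM over all barcodes, against at least 12220 CPM in the other libraries. The missing NK-like clusters alone do not measure the NK cell share of these libraries, but the marker sums argue against a large one. The spleen comparison of gene expression therefore has 1 control mouse and 2 CML mice, except under alternatives that bring cells of these libraries back in.

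**Figure D1:**
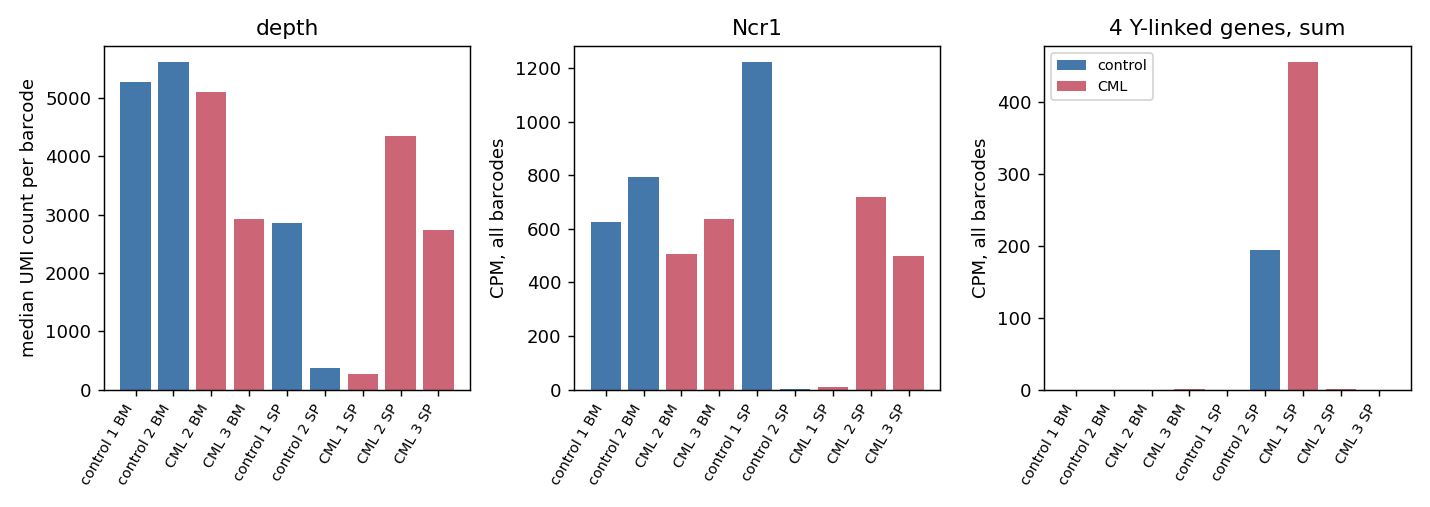
Bars give the median UMI count per barcode and the CPM over all barcodes of Ncr1 and of the Y-linked genes, for each library (BM, bone marrow; SP, spleen). Control mouse 2 spleen and CML mouse 1 spleen have the lowest depth and Ncr1 values and the highest Y-linked sums.

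The first question was whether the kinds of NK cell differ between CML and control mice. Mature NK-like cells, with Klrg1, Zeb2, S1pr5 and Cx3cr1 high, made up 77.3% of the filtered spleen cells of control mouse 1 (Wilson 95% interval 76.1 to 78.4), and 26.1% (25.0 to 27.1) and 10.4% (9.60 to 11.2) in CML mice 2 and 3. ILC1-like cells, with Tmem176b, Cxcr6 and Gzmc high, made up 0.830% (0.613 to 1.12) of the control spleen, and 7.30% (6.70 to 7.96) and 20.2% (19.2 to 21.3) of the CML spleens. Cycling cells made up 1.72% of the control spleen and 9.65% and 8.81% of the CML spleens. Interferon-stimulated cells made up 0.628% of the control spleen and 1.20% and 1.30% of the CML spleens. Without CML mouse 3 the ILC1-like difference in spleen was 6.47 percentage points, against 12.9 with both CML mice. The intervals cover counting error only, and an exact two-sided permutation test of 2 mice against 1 cannot go below 0.333. This test gave 0.667 for the ILC1-like share and 0.333 for each of the other classes. As a share of the kept cells the ILC1-like difference in spleen was 19.9 points, and cycling cells made up 1.75% in control and 11.9% and 14.1% in CML mice. The unnamed kept clusters 3, 6, 7 and 19 held 13.2%, 0.324%, 3.79% and 0.486% of the filtered control spleen cells. They held 21.0%, 1.86%, 11.3% and 2.53% in CML mouse 2 spleen, and 13.9%, 0.302%, 6.27% and 1.12% in CML mouse 3 spleen. The shares of these clusters were not tested.

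In bone marrow, ILC1-like cells made up 5.73% and 6.06% of the cells in control mice and 12.8% and 32.4% in CML mice, a difference of 16.7 percentage points. Mature NK-like cells made up 6.83% and 3.04% in control and 2.38% and 1.95% in CML mice. Cycling cells made up 11.3% and 7.85% in control and 11.4% and 17.1% in CML mice. Interferon-stimulated cells made up 1.06% and 2.08% in control and 1.41% and 0.813% in CML mice (exact two-sided permutation p 0.667). The exact two-sided permutation p was 0.333 for each of the other classes, which is the smallest that 2 against 2 mice allow, so the shares stand as values. Without control mouse 1 the mature NK-like difference in bone marrow was -0.879 percentage points, and without control mouse 2 it was -4.67, against -2.77 with all mice. Without CML mouse 3 the ILC1-like difference was 6.89 points, and without CML mouse 2 it was 26.5 points. As a share of the kept cells, mature NK-like cells overlapped between groups, at 10.2% and 3.80% in control and 4.52% and 2.67% in CML mice (exact permutation p 0.667). With that denominator the ILC1-like difference in bone marrow was 26.2 points, and cycling cells made up 17.0% and 9.80% in control and 21.6% and 23.3% in CML mice.

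**Figure D2:**
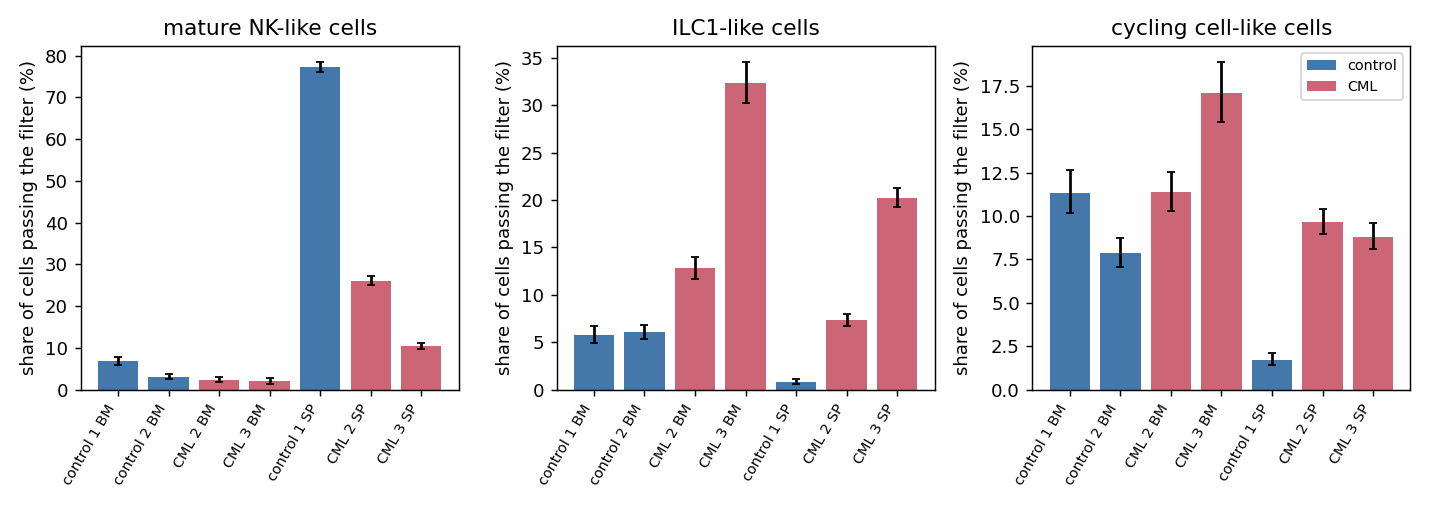
Bars give the share of cells that pass the filter in mature NK-like, ILC1-like and cycling clusters for the 7 libraries with NK-like cells, with Wilson 95% intervals for counting error. Mature NK-like cells are 77.3% in control mouse 1 spleen and 26.1% and 10.4% in the CML spleens.

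The comparison of CML with control spleen asks how host NK cells change their expression beside leukaemia. Genes of mature NK cells fell in the CML mice: S1pr5, a receptor for exit from tissues, by a log2 fold change of -2.27 ± 0.19 (SE), the transcription factor Zeb2 by -2.23 ± 0.24, Cx3cr1 by -2.03 ± 0.17 and Klrg1 by -1.89 ± 0.15. Genes of cell division rose, with Mki67 at 2.24 ± 0.20 and Birc5 at 2.38 ± 0.16. Genes known from ILC1 rose, with Tmem176b at 4.62 ± 1.08 and Il7r, the interleukin-7 receptor, at 3.48 ± 0.55. In all, 1212 of 12158 genes changed at an adjusted p under 0.05 (edgeR), 832 higher and 380 lower in CML.

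These calls and standard errors rest on 1 control mouse, which is assumed to vary like the CML mice, and on which clusters were kept. With the first rule for naming clusters, replaced after its names were seen, 0 genes passed in edgeR (103 at unadjusted p under 0.05). With all cells that pass the filter 0 genes passed (66 unadjusted), or 0 (1662 unadjusted) without control mouse 2 and CML mouse 1. DESeq2 on the same 3 libraries gave 882. A fit of all 7 libraries in 4 groups of condition and tissue, without a block, gave 386; in that form, with the spread taken from the 2 control bone marrow libraries alone, the count was 1 without CML mouse 2 and 0 (1149 unadjusted) without CML mouse 3.

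Of the 15 mature NK genes, 11 fell and 4 were not called (12 adjusted over the list alone). Among them Itgam, which encodes CD11b, fell by 1.25 ± 0.23 on the log2 scale, the protease gene Gzma by 0.94 ± 0.13, and Tbx21, which encodes T-bet, changed by -0.80 ± 0.17. Of the 14 immature NK genes 10 rose (12 adjusted over the list alone). Examples are the chemokine Xcl1 at 1.72 ± 0.18, Kit at 2.12 ± 0.22 and the transcription factor Tcf7 at 1.14 ± 0.14. Tcf7 turned direction under the first naming rule (-0.35) and with all cells (-0.047). Of the 16 ILC1 genes 10 rose (12 adjusted over the list alone), among them Itgb3 at 2.92 ± 0.41 and Inpp4b at 3.02 ± 0.51; Inpp4b stood at -0.18 under the first naming rule. All 26 proliferation genes rose (26 adjusted over the list alone), with Cks1b at 2.24 ± 0.15. In camera with a preset correlation these lists had adjusted p of 3.88e-06, 3.88e-06, 0.000442 and 9.13e-17, and each had adjusted p = 0.682 with an estimated correlation.

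Of the 28 lists 13 passed in spleen at the preset correlation, and 0 with an estimated one, where 1 residual degree of freedom leaves a list hardly able to pass. Other lists held fewer calls. Of 27 cytosolic ribosomal protein genes 5 rose (17 adjusted over the list alone), with Rps2 at 0.85 ± 0.16. Camera gave the ribosomal list an adjusted p of 3.63e-06, and adjusted p = 0.682 with an estimated correlation. Of 19 inhibitory receptor genes 5 rose and 3 fell (6 and 5 adjusted over the list alone): Lag3 was at 2.44 ± 0.31 and Lilrb4a at 2.93 ± 0.21, while Klra9 was at -1.69 ± 0.27; the list did not pass camera (adjusted p 0.356). Of 18 activating receptor genes 2 rose and 2 fell (3 and 11 adjusted over the list alone), with Slamf6 at 2.47 ± 0.26. Its camera adjusted p was 0.0113, and adjusted p = 0.682 with an estimated correlation. Of 18 cytotoxic granule genes 3 rose and 4 fell (5 and 5 adjusted over the list alone), with perforin (Prf1) at -1.12 ± 0.18, and this list did not pass camera either (adjusted p 0.4925). Several genes central to NK function were not called: Ifng 0.01 ± 0.25, Gzmb -0.10 ± 0.17, Ncr1 -0.44 ± 0.16, Klrk1 -0.52 ± 0.18, Eomes -0.43 ± 0.21, Cd27 0.52 ± 0.14 and Tgfb1 0.05 ± 0.13. Outside the lists the largest falls included Rac3 at -2.58 ± 0.24, and the largest rises Plac8 at 2.90 ± 0.20 and Hist1h1b at 2.91 ± 0.29. Lag3 turned direction under the first naming rule (-0.81), and with all cells and the replicate number as a block Lag3 stood at -0.084 and Klra9 at 0.21.

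Markers of other blood cells moved with CML in the same spleen cells. Of 9 neutrophil genes tested 7 rose (9 adjusted over the list alone). S100a9, S100a8 and Ngp had 0 counts in the control and were at least 340.6-fold, 243.7-fold and 63.6-fold higher in CML, by the mean of the CML mice against a floor of 3 counts in the control library. In CML mouse 2 alone, without CML mouse 3, these bounds were 158.8, 119 and 29.9. The levels behind these folds were low. In CML mice 2 and 3 S100a9 stood at 29.0 and 95.4 CPM, S100a8 at 21.7 and 67.3 CPM, and Ngp at 5.47 and 17.8 CPM. Whether the kept cells themselves carried these transcripts was not tested. The neutrophil list's median log2 fold change was 9.54 as fitted and 5.34 with genes at 0 taken at their bound. Of 14 T cell genes 6 rose (11 adjusted over the list alone), with Cd3g at 2.02 ± 0.17 and Cd3d at 1.92 ± 0.17. All 5 dendritic cell genes rose (5 adjusted over the list alone), including H2-Ab1 at 3.02 ± 0.44, and 3 of 8 B cell genes rose (6 adjusted over the list alone), including Igkc at 7.66 ± 1.74. Of 6 erythroid genes 1 rose and 4 fell (1 and 4 adjusted over the list alone), with Hbb-bs at -4.15 ± 0.32. Cd3g stood at -0.15 under the first naming rule, H2-Ab1 at -0.65 with clusters made without the defining genes when the shallow libraries entered, and Hbb-bs at 0.86 with all cells. Clusters removed before the comparison included a neutrophil-like cluster with 12.6% of the filtered CML mouse 3 and 0.227% of the CML mouse 2 spleen cells, and a B cell-like cluster, led by Igkc and Jchain, with 5.72% and 0.454%. A T cell-like cluster, number 8, held 13.1% and 9.77% of them and 0.810% of the control spleen cells. Camera gave the neutrophil, T cell, dendritic, B cell and erythroid lists adjusted p of 1.24e-06, 1.62e-06, 0.00244, 0.00604 and 0.0112, and each had adjusted p = 0.682 with an estimated correlation. Of 4 progenitor genes, from a list that shares Kit with the immature NK list, 2 rose (2 adjusted over the list alone). Of 4 basophil and mast cell genes 0 passed (2 rose adjusted over the list alone). The progenitor and the basophil and mast cell lists had camera adjusted p of 0.0223 and 0.0131, and 0.682 for each with an estimated correlation. Of 6 monocyte and macrophage genes 2 fell (1 rose and 2 fell adjusted over the list alone), with a camera adjusted p of 0.914.

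Within single clusters, which were built from the same expression values, the median difference of the mature NK list between CML and control spleen was smaller than the -1.05 over all kept cells. In the mature NK-like cluster 62 of 10402 genes changed between CML and control, and the median log2 fold change of the mature NK list was -0.14. In an unnamed cluster, number 3, 90 genes changed and that median was 0.09. In another, number 7, 4 genes changed and the median was -0.32. The ILC1 list had medians in these clusters of 0.98, 0.79 and 0.29, against 2.52 over all kept cells. The proliferation list had medians of 0.54, 0.54 and 0.29, against 1.78.

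The same comparison in bone marrow, 2 CML against 2 control mice, had no gene past the threshold over all kept cells. S1pr5 stood at -2.43 ± 0.30, Zeb2 at -2.05 ± 0.25 and Klrg1 at -1.66 ± 0.35. The ILC1 genes Itgb3, Inpp4b and Tmem176b stood at 1.89 ± 0.23, 1.46 ± 0.22 and 2.21 ± 0.43. Mki67 was at 0.77 ± 0.35 and Ifng at -0.17 ± 0.24. edgeR called 0 of 11313 genes (1109 at unadjusted p under 0.05, smallest adjusted p 0.0737), and DESeq2 called 87. Without control mouse 1 the count was 985 and without control mouse 2 it was 146; it was 1 without CML mouse 2 and 0 (416 unadjusted) without CML mouse 3. Within single clusters edgeR called 52 genes in the ILC1-like cluster, where the median log2 fold change of the mature NK list was -0.71. It called 30 in cluster 3 and 6 in cluster 7, with medians of 0.048 and -0.05, and 3 and 1 in the cycling clusters, with medians of -0.55 and -0.52.

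As groups, 9 of the 28 lists passed camera in bone marrow at a preset correlation. With an estimated one, on 2 residual degrees of freedom, 0 passed and the smallest adjusted p was 0.677. The count at a preset correlation was 15 without control mouse 1. Of 14 mature NK genes 0 passed over all genes and 9 fell adjusted over the list alone, with a median of -1.19 and a camera adjusted p of 3.74e-07. Of 15 ILC1 genes 0 passed and 7 rose adjusted over the list alone, with a median of 0.53 and an adjusted p of 0.00151. Of 22 homing genes 0 passed and 11 fell adjusted over the list alone, with a median of -0.46 and an adjusted p of 9.73e-06. For these lists the adjusted p was 0.677 with an estimated correlation. All 26 proliferation genes were higher without passing, 0 adjusted over the list alone, with a median of 0.46 and an adjusted p of 4.90e-05 (adjusted p = 0.702 with an estimated correlation). Of 19 immediate early genes 0 passed, 1 rose and 7 fell adjusted over the list alone; Fos stood at -2.03 ± 0.49 and Zfp36 at -1.02 ± 0.18. Of the filtered cells of control mouse 2 bone marrow, 50% lay in cluster 6, with Nr4a2, Junb and Rgs2 among its top genes, and the median of the immediate early list was 0.554 higher there than in control mouse 1. Of 9 neutrophil genes 0 passed and 5 rose adjusted over the list alone, with a median of 2.50 and S100a8 at 2.50 ± 0.71. Among the remaining genes Gzma was at 0.03 ± 0.28, Gzmb at 0.20 ± 0.44, Prf1 at -0.99 ± 0.31, Ncr1 at -0.27 ± 0.16, Klrk1 at -0.38 ± 0.14, Eomes at -0.07 ± 0.15, Tbx21 at -0.28 ± 0.19, Cd27 at -0.42 ± 0.17, Itgam at -1.28 ± 0.32 and Tgfb1 at -0.16 ± 0.16. The immediate early and neutrophil lists had camera adjusted p of 0.00383 and 1.16e-05, each with adjusted p = 0.677 with an estimated correlation. All 5 dendritic cell genes were higher, 0 past the threshold and 4 adjusted over the list alone, with a median of 0.71, a camera adjusted p of 0.00679 and adjusted p = 0.677 with an estimated correlation. Of 18 activating receptor genes 16 were lower, 0 past the threshold and 4 adjusted over the list alone. Of 23 type I interferon genes 17 were lower, 0 past the threshold and 0 adjusted over the list alone, while in spleen 17 of 23 were higher. In bone marrow these lists had camera adjusted p of 8.12e-05 and 0.0183, and 0.677 and 0.772 with an estimated correlation.

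**Figure D3:**
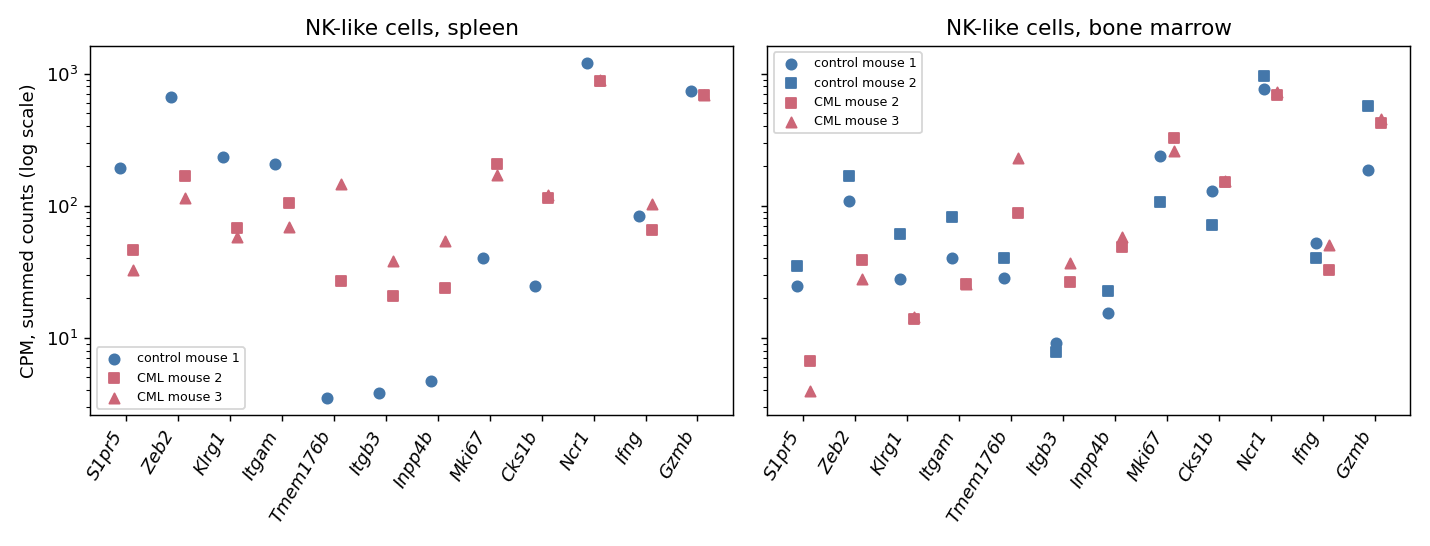
Points give the CPM (log scale) of selected genes in the summed counts of NK-like cells of each mouse, spleen on the left and bone marrow on the right. S1pr5 and Zeb2 lie lower in every CML mouse than in every control mouse in both tissues, with 1 control mouse in spleen and none of the bone marrow genes past the threshold.

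The comparison of spleen with bone marrow, within 3 mice, asks how host NK cells differ by tissue. Several mature NK genes were higher in spleen cells: Cx3cr1 by 3.42 ± 0.22 on the log2 scale, S1pr5 by 2.87 ± 0.10, Klrg1 by 2.47 ± 0.21 and Zeb2 by 2.22 ± 0.13. Itgam was higher by 1.93 ± 0.18 and the protease gene Cma1 by 2.63 ± 0.27. Ifng, the gene of interferon gamma, was higher in spleen by 0.85 ± 0.09, and Lyst was lower, at -1.13 ± 0.07. Each of these genes had the same direction in 3 of 3 mice. The naming rule required this of the largest rises and falls, so for those it is no further support. The cells also lay in different clusters by tissue. Mature NK-like cells made up 77.3%, 26.1% and 10.4% of the filtered spleen cells in control mouse 1 and CML mice 2 and 3. In their bone marrow they made up 6.83%, 2.38% and 1.95%. In all 54 of 11532 genes changed (edgeR, adjusted p under 0.05), 45 higher and 9 lower in spleen.

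That count moved with the cells and mice used. It was 0 under the first naming rule (edgeR, 890 at unadjusted p under 0.05), 0 with all cells (753 unadjusted), 0 without the mouse as a block (1208 unadjusted), and 485 with DESeq2, of which 46.2% were higher in spleen against 83.3% in edgeR. Without control mouse 1 it was 2118, without CML mouse 2 it was 2 and without CML mouse 3 it was 27.

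Of the 28 lists 10 passed camera between tissues at the preset correlation. With an estimated one, on 2 residual degrees of freedom, 0 passed and the smallest adjusted p was 0.678. Of 14 mature NK genes 7 rose in spleen (13 adjusted over the list alone), with a camera adjusted p of 1.26e-10 and adjusted p = 0.678 with an estimated correlation. All 27 ribosomal protein genes were lower in spleen, 0 past the threshold and 0 adjusted over the list alone, with a median of -0.35, a camera adjusted p of 5.91e-08 and adjusted p = 0.678 with an estimated correlation. Of 21 immediate early and dissociation stress genes 0 passed (10 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 0.0364 and adjusted p = 0.691 with an estimated correlation. Of 22 homing genes 4 rose (12 higher and 5 lower adjusted over the list alone), among them Itga4 at 1.22 ± 0.10 and Klf2 at 1.25 ± 0.13, with an adjusted p of 0.0123 and adjusted p = 0.678 with an estimated correlation. Of 10 cytokine and chemokine genes 2 rose (5 adjusted over the list alone), Ifng and Ccl5 at 1.19 ± 0.15, with an adjusted p of 0.103. The activating receptor gene Slamf7 rose by 1.01 ± 0.12. The inhibitory receptor gene Klra3 rose by 0.69 ± 0.08, and stood at -0.15 under the first naming rule and -0.082 with all cells. All 26 proliferation genes were lower in spleen, 0 past the threshold and 10 adjusted over the list alone, with Mki67 at -1.29 ± 0.39 and a camera adjusted p of 1.40e-07 and adjusted p = 0.678 with an estimated correlation. That fit gives control and CML mice a shared spleen effect, while the CML effect on these genes differed between tissues by a median of 1.70. Cycling cells made up 1.72% of spleen and 11.3% of bone marrow cells in control mouse 1. In CML mice 2 and 3 they made up 9.65% and 8.81% of spleen cells and 11.4% and 17.1% of bone marrow cells. Not called were Gzma at 0.97 ± 0.32, Gzmb at 1.04 ± 0.27, Prf1 at 1.39 ± 0.19, Ncr1 at 0.39 ± 0.11, Klrk1 at 0.25 ± 0.09, Eomes at -0.19 ± 0.14, Tbx21 at 0.69 ± 0.10, Cd27 at -0.26 ± 0.20 and Tgfb1 at -0.04 ± 0.09.

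Whether the CML effect differed between tissues was tested directly, in the 3 mice with both tissues. Cell division genes stood out: the CML effect in spleen exceeded that in bone marrow by a log2 difference of 2.48 ± 0.10 for Hist1h1b, 2.25 ± 0.11 for Pclaf, 1.93 ± 0.10 for Mki67 and 2.16 ± 0.12 for Birc5. Ly6c2, a surface protein gene of monocytes and some lymphocytes, went the other way at -2.10 ± 0.11. Of 26 proliferation genes 26 differed in this direction (26 adjusted over the list alone), with a camera adjusted p of 7.15e-20 and adjusted p = 0.697 with an estimated correlation. All 27 ribosomal protein genes differed too (27 adjusted over the list alone), with a median of 0.43, a camera adjusted p of 1.44e-08 and adjusted p = 0.697 with an estimated correlation. Of 15 mature NK genes 12 had a lower and 1 a higher CML effect in spleen (12 and 1 adjusted over the list alone), with a camera adjusted p of 0.000296 and adjusted p = 0.697 with an estimated correlation. Of 14 immature NK genes 13 had a higher CML effect in spleen (13 adjusted over the list alone), with a camera adjusted p of 4.40e-05 and adjusted p = 0.697 with an estimated correlation. Of 16 ILC1 genes 12 had a higher and 1 a lower effect (12 and 1 adjusted over the list alone), with 0.00207 and adjusted p = 0.791 with an estimated correlation. Markers of other cell types went in several directions. Higher were 5 of 5 dendritic cell, 3 of 9 neutrophil, 4 of 14 T cell and 2 of 4 progenitor genes (5, 4, 5 and 2 adjusted over the list alone). Their camera adjusted p were 0.0267, 0.00672, 0.0338 and 0.0215, and adjusted p = 0.789, 0.697, 0.803 and 0.697 with an estimated correlation. Of 6 monocyte and macrophage genes 1 was higher and 2 lower (1 and 3 adjusted over the list alone), of 8 B cell genes 2 and 2 (2 and 2), and of 6 erythroid genes 1 and 1 (1 and 1), with medians of -0.42, 0.32 and -0.57, and none of these lists passed camera. Of 21 immediate early and dissociation stress genes 11 were higher and 0 lower (11 and 1 adjusted over the list alone), with a camera adjusted p of 0.000319 and adjusted p = 0.697 with an estimated correlation. In all 1854 of 12032 genes differed (edgeR), 1266 with a higher and 588 with a lower CML effect in spleen.

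That count, like the ± values above, has the same single control mouse behind it and a spread estimated with 1 residual degree of freedom. It was 0 with all 7 libraries in 4 groups without a block (762 at unadjusted p under 0.05), 0 under the first naming rule (282), 0 with all cells (146) and 9 without the mouse as a block, all in edgeR, and 289 in DESeq2, of which 93.8% had a higher CML effect in spleen against 68.3% in edgeR. With 1 CML mouse left out the blocked test has no residual degrees of freedom and gives no p-value. Without cells of high UMI count Hist1h1b stood at -0.46, and Hist1h2ap at -1.42 passed the threshold in the opposite direction. That cut falls on cycling cells: the cycling clusters had median UMI counts of 9089 and 12509, against 2653 to 5430 in the other kept clusters. It removes cells that carry these genes, so the turn cannot decide whether doublets made the result. With clusters made without the defining genes Pclaf stood at -0.47 and Mki67 at -0.71 when the shallow spleen libraries entered; without those libraries all 8 genes named for this comparison kept direction and call, and 1733 genes passed.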

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

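The tests on the libraries without NK-like cells were chosen after those results were seen; the test of the difference between tissues was planned, while its form without a block over 7 libraries and the set without cells of high UMI count were chosen after its result was seen.

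The spleen libraries of control mouse 2 and CML mouse 1 stood out in data that the comparisons do not use: their Y-linked genes summed to 193.9 and 454.7 CPM, and to at most 0.144 CPM in the other 7 libraries. Xist stood at 195.8 CPM in control mouse 2 spleen and 2.84 CPM in CML mouse 1 spleen, and at 695.7 to 1379 CPM in the others, among them control mouse 2 bone marrow, with a Y-linked sum of 0.0364 CPM over the 2 genes it lists. Cells of other animals are a candidate source; cells of the transplant donor stay open as well, although the sort for host NK cells in the labels would remove them, and its CD3-negative gate would remove T cells. Different chemistry or processing may also be involved, since Actb in T cell-like clusters was at least 17.98 times as high as in any other library. Low depth alone could not be decided: the NK marker sum was at most 0.1034 of the lowest other spleen library, between the bounds of 0.5 and 0.1 set for this test, although Ncr1 at 3.62 and 11.1 CPM, against at least 499.1, was far below; no biological explanation was tested.

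The CML effect differed between spleen and bone marrow, by the interaction test, for 8 genes singled out by the smallest p. The log2 differences, spleen minus bone marrow, were 2.48 for Hist1h1b, 2.25 for Pclaf, -2.10 for Ly6c2, 1.93 for Mki67, 2.16 for Birc5, 1.73 for Hist1h2ap, 1.76 for Dut and 2.00 for Cks1b. They rest on 1 control mouse. Without cells of high UMI count Hist1h2ap was at -1.42, past the threshold in the opposite direction, and Hist1h1b at -0.46, not past it. That cut falls on the cycling clusters, with median UMI counts of 9089 and 12509, so it removes cells that carry these genes and does not test the difference. With all 7 libraries in 4 groups and no block edgeR called 0 genes (762 at unadjusted p under 0.05), and DESeq2 with the block called 289.

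Control mouse 2 bone marrow carries antibody tags that the comparisons do not use. Their median counts per cell were 60 for CD11b, 185 for CD27, 122 for CD122, 170 for NK1.1 and 153 for TCRb. The TCRb tag did not separate the clusters, with 157 in a T cell-like cluster and 156 in the mature NK-like cluster. No isotype or empty-droplet background was used here, so these counts are not read as protein levels.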

How the results depend on the processing

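Alternatives on cluster naming, cluster 4, the ILC1-like cluster, cells of high UMI count, clusters without defining genes, all cells with a replicate block and the sets without the shallow spleen libraries were chosen after seeing the data, as were the shares over all 5 spleen libraries, of the kept cells and without each mouse, and genes not listed for control mouse 2 taken as 0; the others were planned. Except for clusters made without defining genes, the cause was not tested. Counts are of genes past the threshold in edgeR unless DESeq2 is named.

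In spleen the count of 1212 became 2440 with no gene filter, 387 with a mean of at least 50 CPM and 386 with all libraries in 1 fit of 4 groups. It became 2064 with the ILC1-like cluster removed and 602 without cells of high UMI count. It was 0 with all cells (66 at unadjusted p under 0.05), 0 with all cells and a replicate block (27), 0 under the first naming rule (103), 0 with clusters made without defining genes (138) and 0 with all cells but without the 2 shallow spleen libraries (1662). The clusters made without defining genes gave 998 once those libraries were left out, 991 of them among the 1212. It was 882 in DESeq2. Without each CML mouse it ranged from 0 to 1, with 0 lacking CML mouse 3 and 1 lacking CML mouse 2; these are fits of 4 groups with the spread from the 2 control bone marrow libraries, to be set against 386 and not 1212. No fit without the control was possible. In bone marrow the count of 0 (1109 unadjusted) became 87 in DESeq2, 522 with no gene filter, 5 after thinning, 9 with cluster 4 kept and 21 without cells of high UMI count. Leaving out each mouse gave 0 to 985, with 985 lacking control mouse 1, 146 lacking control mouse 2 and 1 lacking CML mouse 2.

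Between tissues the count of 54 became 485 in DESeq2, 1188 with no gene filter, 5 with a mean of at least 50 CPM, 19 with at least 1000 genes per cell, 646 with the ILC1-like cluster removed and 571 without cells of high UMI count. It was 0 with all cells (753), 2 with all cells but without the shallow spleen libraries, 0 under the first naming rule (890) and 0 with clusters made without defining genes (623), where leaving out the shallow libraries gave 50, 49 of them among the 54. Leaving out each mouse gave 2 to 2118: 2118 lacking control mouse 1, 2 lacking CML mouse 2 and 27 lacking CML mouse 3. For the difference of the CML effect the count of 1854 became 289 in DESeq2, 765 with a mean of at least 50 CPM, 1156 with at least 1000 genes per cell, 760 after thinning, 598 with cluster 4 kept, 1227 with the ILC1-like cluster removed and 650 without cells of high UMI count. It was 0 with all cells (146), 0 with all cells but without the shallow spleen libraries (1175), 0 under the first naming rule (282) and 0 with clusters made without defining genes (115), where leaving out the shallow libraries gave 1733, 1698 of them among the 1854. With all 7 libraries in 4 groups and no block it was 0 (762), a form chosen after seeing the data. In that form it ranged from 0 to 0 without each CML mouse (164 and 376 unadjusted), which says nothing on single mice, since the count with all mice is 0; with the block no such fit has residual degrees of freedom. Without the mouse as a block, the pairing of both tissues, the count between tissues was 0 (1208 unadjusted) and that for the CML effect was 9.

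Lists past camera's threshold numbered 13 in spleen, 9 in bone marrow, 10 between tissues and 12 for the difference. With an estimated correlation these became 0, 0, 0 and 0, with smallest adjusted p of 0.682, 0.677, 0.678 and 0.697. That form uses 1 or 2 residual degrees of freedom, so the loss does not show that correlation between genes explains a list. It does not exclude this either, since some lists had estimated correlations far above the preset one. Leaving out each mouse gave 14 to 17, 8 to 15 (15 lacking control mouse 1), 10 to 15 and 11 to 15 lists, for spleen and for the difference in the 4-group form. The mature NK-like share in spleen differed by -26.5 points over all 5 spleen libraries, against -59.1; the shallow libraries enter it at 0.

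Single genes that turned direction in spleen were Kcnj8 (0.44), Lag3 (-0.084) and Klra9 (0.21) with all cells and a replicate block; Tcf7 (-0.047) and Hbb-bs (0.86) with all cells; and Hbb-bs (0.28) without the shallow libraries. Under the first naming rule they were Tcf7 (-0.35), Inpp4b (-0.18), Lag3 (-0.81), Cd3g (-0.15) and Cish (-0.86). With clusters made without defining genes they were H2-Ab1 (-0.65) and Cd74 (-1.11). Between tissues Klra3 was at -0.082 with all cells, -0.15 under the first naming rule and -0.049 with clusters made without defining genes. For the difference, Hist1h1b was at -0.46 and Hist1h2ap at -1.42 without cells of high UMI count, the latter past the threshold. That cut falls on the cycling clusters, which had the highest median UMI counts of the kept clusters. Pclaf was at -0.47 and Mki67 at -0.71 with clusters made without defining genes. Depth limits what control mouse 2 and CML mouse 1 spleen can show, with medians of 361 and 272 UMI counts per barcode. No gene named here turned direction with clusters made without defining genes once the shallow libraries were left out. Of the other gene values 1569 kept direction and side of the threshold, or were uncalled throughout, 530 lost the call and 104 gained it.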

Other observations

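The test of cluster shares was written before its result was seen, though shares and fold changes had been seen apart; the counts over gene lists were planned, and the tests of depth, of the single control, of control mouse 2 bone marrow and of other splits were chosen after the result was seen.

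Single genes of further lists changed in the CML spleen comparison, while none of these lists passed camera at the preset correlation. Of 12 cytokine and chemokine genes 3 rose and 1, Ccl5, fell (5 and 1 adjusted over the list alone), with Ccl5 at -0.73 ± 0.15. Of 21 immediate early genes 7 rose (8 rose and 1 fell adjusted over the list alone), with Nr4a1 at 2.54 ± 0.27. Of 26 cytokine receptor and JAK-STAT feedback genes 3 rose and 1 fell (3 and 2 adjusted over the list alone); the feedback inhibitors Socs1 and Cish stood at 1.36 ± 0.18 and 2.27 ± 0.40, and Cish at -0.86 under the first naming rule. Of 14 glycolysis genes 3 rose (4 adjusted over the list alone), with Ldha at 1.14 ± 0.20. Of 22 homing genes 2 rose and 5 fell (5 and 7 adjusted over the list alone), with Klf2 at -1.31 ± 0.18. Of 23 type I interferon genes 3 rose and of 25 interferon-gamma response genes 1 rose (3 and 1 adjusted over the list alone). Of 23 oxidative phosphorylation genes 0 passed in edgeR, and 0 adjusted over the list alone, with 20 of them higher. The camera adjusted p were 0.293 for cytokine, 0.0717 for immediate early, 0.989 for cytokine receptor, 0.0780 for glycolysis, 0.183 for homing, 0.0717 and 0.224 for the interferon and 0.0915 for the oxidative phosphorylation genes. In bone marrow Cish stood at 2.31 ± 0.34 without passing, at an adjusted p of 0.173.

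Lower mature NK genes in CML spleen, a median log2 fold change of -1.05 over the list, may mostly follow the shift of cells between clusters. With each cluster's profile held equal and only the shares changed, the median was -0.88, and in the same way it was 1.75 of 1.78 for proliferation, 1.18 of 1.48 for immature NK, 1.55 of 2.52 for ILC1 and 0.28 of 0.49 for ribosomal protein genes; the clusters were built on expression, so this test is partly built in. After thinning the summed counts to one total the median was -1.14. Thinning sums leaves the expected CPM of each gene unchanged, so this cannot decide whether the depth of single cells played a part. Whether the lone spleen control stands apart stays open: the bone marrow median without that mouse was -1.40, but this rests on control mouse 2 alone, a library with a cluster mostly its own. A difference between CML and control mice stays open beside it.

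In control mouse 2 bone marrow 50% of the filtered cells lay in cluster 6, of which 90.9% came from that library. An immediate early or dissociation response may be one candidate explanation: the list's median against control mouse 1 bone marrow was 0.554, only just above the bound of 0.5, which was written after the genes of cluster 6 had been seen. Processing of the whole matrix, which holds estimated counts, stays open: the 37.5% of its kept cells in clusters shared with other libraries are only the rest of the same pattern and decide nothing. Nr4a2, Junb and Rgs2 are among the top genes of that cluster. No biological explanation was tested.

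The 6 libraries of the tissue comparison can be split into groups of 3 in 10 ways, of which 4, the real one included, part all 3 mice; the other 6 part 1 mouse and, with the mouse as a block, test another contrast. The real split, with 54 genes, was the 1 with as many, and the highest of the others was 0, among the 4 as among the 10. With so few splits a share under 0.05 cannot be reached.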
